A study of Mus musculus with 4 samples.

How the data were processed

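Pan T cells were separated magnetically from the spleens of 4 mice, 2 wild-type (WT) and 2 lacking the microRNA miR-146a (KO), all of strain C57BL/6 per the labels. All mice had received an anti-PD-1 antibody 2 times a week for 3 weeks and low-dose LPS 1 time a week, and cells were taken on day 22. Each mouse gave 1 droplet library with 10x Genomics 3′ chemistry, which counts unique molecular identifiers (UMIs) near the 3′ end of polyadenylated transcripts. The genotype and the number of each mouse came from the sample titles. The labels gave no batch, date or sex.

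The deposited values are UMI counts per gene and cell barcode, not normalised, in filtered matrices holding 16208 barcodes in all. Per the submitters' processing notes, reads were handled with bcl2fastq 2.20.0.422 and Cell Ranger 3.1.0 on the mouse build mm10. The annotation behind the counts and any read filter were not given in the sources used here. The lowest total per barcode was 500 or 501 UMIs in each library, a floor already present in the deposited counts. Features were matched by identifier to GENCODE M21 on the same assembly (GRCm38), and 30934 features (99.6%) matched. All coordinates given are on that assembly.

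Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. In each library the cells with the highest Scrublet doublet scores were removed, at 0.8% of barcodes per 1000 barcodes, which took out 236 cells and left 6916. Counts were scaled to 10000 per cell and log-transformed. Clusters came from 2000 variable genes without receptor segment and sex-linked genes, 30 principal components, 15 neighbours and Leiden resolution 1 (scanpy 1.11.5, leidenalg 0.10.2), without integration of libraries. The markers of each cell type were fixed before the data were examined, whereas the percentages of marker-positive cells used to name a cluster were set after the clusters had been seen. A class was compared by name only where none of its clusters had more markers of another class than of its own among its top 10 genes. The naive CD8 class failed this and is given as cluster 1, and the clusters assigned to myeloid and dendritic cells, which failed it too, were pooled as other non-T cells or are given by number.

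UMI counts were summed per mouse and population, since the mouse is the replicate, and tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) with TMM scaling and the default filterByExpr filter. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Standard errors were the absolute log2 fold change divided by the square root of the F statistic of the same fit. They therefore add no information to the p-value. A population was tested only with at least 50 cells in every mouse, except in added fits of cluster 3, with 40 cells in WT mouse 1, and of cluster 12, with 22 to 37 cells in 3 mice. CPM values are the summed UMIs scaled to the TMM-adjusted total of the genes that passed the filter, given as mean and SD over 2 mice. The difference of the KO effect between CD4-like and CD8-like cells was the interaction term of 1 model with the mouse as a term. Cell numbers per class were tested with edgeR on cells kept, beside an exact two-sided permutation test, which cannot go under 0.333 with 2 against 2.

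The 27 gene lists, the tests and most alternatives were fixed before the data were examined. Lists were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. A fry result tests whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. Genes with a 7-mer or 8-mer match to the miR-146a-5p seed in their longest annotated 3′ UTR were compared in the same way with genes that had a UTR and no match. The named genes of each population were, among changed genes with both KO values on the same side of both WT values and a mean of at least 10 CPM, the 12 with the largest positive and the 12 with the largest negative log2 fold change, plus the 3 members of each list with the smallest adjusted p among those that passed. If fewer than 10 genes passed, the 10 with the smallest p were taken. Receptor and immunoglobulin segments, sex-linked genes and predicted genes were counted but not named under this rule. Traf6, Irak1, Rel, Relb, Icos and Cxcr4 were always named, and 1 further gene of this rule is not reported here.

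Counts with known changes were simulated at the fitted dispersion trend, without repeated draws. The simulation had no shifts in cell mix between mice, and changed genes were drawn from the better-counted ones, so recovery may be optimistic. No gene was called in any of the 4 main populations when none had been changed. With changes present, 6 of 183 calls in all T, 10 of 176 in CD4-like, 7 of 166 in CD8-like and 0 of 118 in regulatory T-like cells were false. Of genes changed 2-fold, 78% were recovered in all T cells, 77.6% in CD4-like, 83.7% in CD8-like and 44% in regulatory T-like cells. The interaction test recovered 64% of 2-fold differences, with 4 false calls. The share test recovered 39% of 2-fold changes in 100 draws at an assumed overdispersion of 0.05.

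Alternatives covered DESeq2 1.42.0, RLE size factors, no filter on low counts, robust estimation, doublets kept, other limits on genes and mitochondrial UMIs, the mouse number as a block, each mouse left out, other clusterings and classes from marker UMIs per cell. Added after seeing the data were clusters made without the 140 genes called in any population, fits without genes at least 20 times more abundant in another lineage, fits without the regulatory or the interferon-responding clusters, and separate fits of the 2 regulatory clusters and of the 2 memory or effector CD8-like clusters. A limit of 5% mitochondrial UMIs left too few cells for CD4-like, CD8-like and regulatory T-like cells.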

Results

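The transcriptomes of splenic T cells were compared between 2 WT mice and 2 mice lacking miR-146a, a microRNA known to restrain NF-kB signalling, after treatment with an antibody that blocks the checkpoint receptor PD-1 and with low-dose LPS to induce immune-related side effects. The libraries held 13266318 and 16427991 UMIs in WT mice 1 and 2 and 17072166 and 14999615 in KO mice 1 and 2. After filtering, 1438 and 1922 WT cells and 1915 and 1641 KO cells remained, with a median of 5084 to 5680 UMIs. The median mitochondrial share over all barcodes was 24.2% in KO mouse 1 and 11.4% to 13.8% in the other libraries. Replicates were distinct libraries, with chi-square per degree of freedom of 4.89 between the WT and 4.33 between the KO mice. Xist, the transcript that silences an X chromosome in females, had 6691 to 9220 UMIs in each library, and Ddx3y, Eif2s3y, Kdm5d and Uty had 0 to 3.

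The targeted gene Mir146 lies on chromosome 11 at 43374397 to 43374461 on the minus strand, and 0 of the counted features carried its name, so the genotype labels were not checked by it. Of 6 tested genes neighbouring Mir146, 0 changed in all T cells by edgeR, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05. The cells formed 28 clusters, 13 of them T cells with 5483 cells. Non-T cells numbered 274 of 1438 and 308 of 1922 in the WT mice and 461 of 1915 and 390 of 1641 in the KO mice.

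In all T cells, Penk, which encodes the opioid precursor proenkephalin (chromosome 4, 4133531 to 4138819), rose from 3.28 ± 0.015 to 35.4 ± 8.9 CPM (SD, n = 2 per genotype), a log2 fold change of 3.42 ± 0.22 (SE; edgeR adjusted p = 2.7e-05). Tnfrsf4, the costimulatory receptor OX40 (chromosome 4, 156013843 to 156016612), rose by 1.14 ± 0.10 (edgeR adjusted p = 0.00035), from 57.1 ± 8.3 to 127 ± 8.3 CPM. Maf, a transcription factor of helper and regulatory subsets, rose by 0.86 ± 0.09, and Ikzf2, the Helios transcription factor, by 0.62 ± 0.07. Pdcd1, which encodes PD-1 itself, rose from 26.4 ± 2.9 to 43.2 ± 2.4 CPM, a log2 fold change of 0.72 ± 0.11 (edgeR adjusted p = 0.012). In total 77 of 10854 tested genes changed, 53 higher and 24 lower in KO. The WT and KO values of all 77 did not overlap. The call itself selects genes with a wide gap between the groups, so this adds no support. For a gene that was not selected, chance alone gives it with a probability of 0.333 with 2 against 2. DESeq2 called 38 genes, 36 of them among the 77, and 38 of the 77 were still called without WT mouse 2. The count was 3 at a limit of 5% mitochondrial UMIs, where 67 of 68 tested genes kept their sign. Those cells came from the same mice and were largely among the cells already used, so the kept signs are no separate support.

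Of 23 tested regulatory T cell genes, 10 rose and 0 fell over all genes tested, and 16 rose when adjusted over the list alone. The list's median log2 fold change was 0.62 (limma camera adjusted p = 6.2e-35, and adjusted p = 0.229 with an estimated correlation). Among its members Capg, an actin-capping protein, rose by 0.96 ± 0.13, Klrg1, an inhibitory receptor of differentiated lymphocytes, by 1.34 ± 0.16, and Tnfrsf18, the receptor GITR, by 0.53 ± 0.07. Without the regulatory clusters, 20 genes remained called in all T cells and the median of the list was 0.30. Activation and checkpoint genes rose in 7 of 26 tested members and in 11 when adjusted over the list alone, where 2 fell, with a median of 0.26 (camera adjusted p = 6.5e-13, and adjusted p = 0.35 with an estimated correlation). Icos, an inducible costimulatory receptor and reported miR-146a target, rose by 0.50 ± 0.10 (edgeR adjusted p = 0.0447). A UMI of Icos was found in 23.5% and 22.6% of WT T cells and in 22.6% and 29.6% of KO T cells, for mice 1 and 2. In cluster 1 these shares were 17.6% and 16.4% in WT and 9.47% and 12.7% in KO mice. Of 29 NF-kB response genes, Tnip1, an inhibitor of NF-kB signalling, rose by 0.56 ± 0.11 and Cd83, an activation marker, by 1.15 ± 0.17. No other member of that list passed over all genes, and 9 rose when adjusted over the list alone, with a median of 0.24 (camera adjusted p = 8.7e-09, and adjusted p = 0.35 with an estimated correlation). B cell transcripts moved with these groups: 3 of 14 B cell markers rose over all genes and 5 when adjusted over the list alone, among them Cd74, the class II invariant chain, by 0.99 ± 0.14 (camera adjusted p = 6.7e-07 for the list, and adjusted p = 0.35 with an estimated correlation). Cd74 was 404 times more abundant in another lineage. Red cell markers and monocyte and macrophage markers each had a median of 0.26, with 0 of 10 members passing in edgeR and 2 of 10 at an unadjusted p under 0.05. A UMI of the immunoglobulin gene Igkc was found in 78.4% and 77.6% of WT T cells and in 91.5% and 81.4% of KO T cells. In non-T cells these shares were 81.0%, 84.1%, 94.4% and 81.8% in the same order. Median depths in T cells were 5468, 5505, 5054.5 and 5602 UMIs. For the myeloid marker Lyz2 the shares of T cells were 6.36%, 5.76%, 10.7% and 10.4%. For the plasma cell marker Jchain they were 13.7%, 17.8%, 27.3% and 18.5%. S100a8, at 12.3%, 21.4%, 16.1% and 20.3%, and Hbb-bs, at 98.2%, 98.5%, 99.2% and 97.4%, did not separate the genotypes.

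Of 43 tested genes of the type I interferon response, 5 fell and 1 rose over all genes in all T cells, and 17 fell and 1 rose when adjusted over the list alone. The list's median was -0.28 (camera adjusted p = 1.5e-14, and adjusted p = 0.229 with an estimated correlation). Ifi27l2a, an interferon-induced gene, fell from 608 ± 15 to 420 ± 23 CPM, a log2 fold change of -0.53 ± 0.07 (edgeR adjusted p = 0.0077). Ifit1, an interferon-induced sensor of viral RNA, changed by -0.94 ± 0.14, but stood at 0.20 at a limit of 5% mitochondrial UMIs. Ifi206, Ifi213 and Ifi214, of the interferon-inducible p200 family, changed by -0.54, -0.59 and -0.52. Ly6a, the surface antigen Sca-1, was the member that rose, by 0.56 ± 0.07. Outside this list, Dnaja1 and Hsph1, both chaperones, changed by -0.45 ± 0.08 and -0.79 ± 0.14.

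Tpm3-rs7, a tropomyosin 3 related sequence on chromosome 14 (113314608 to 113316754), rose from 11.1 ± 1.7 to 260 ± 8.0 CPM, a log2 fold change of 4.56 ± 0.10 (edgeR adjusted p = 6.4e-10). Tpm3, tropomyosin 3 on chromosome 3 (90072649 to 90100902), fell from 414 ± 3.8 to 177 ± 1.0 CPM, a log2 fold change of -1.22 ± 0.06. The 2 sequences are related, so how reads were divided between them is uncertain, and their summed counts had a log2 fold change of 0.04 ± 0.07 (SE). Ide, the insulin-degrading enzyme, rose by 1.03 ± 0.11, and Cdk5rap1, a tRNA-modifying enzyme, changed by -1.66 ± 0.31. All 4 genes changed in the same direction in CD4-like and CD8-like cells.

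In conventional CD4-like cells (486 to 642 per mouse) Ikzf2 rose from 60.1 ± 7.0 to 106 ± 10 CPM, a log2 fold change of 0.81 ± 0.11 (edgeR adjusted p = 0.00016). Tnfrsf4 rose by 0.86 ± 0.16, Tnip1 by 0.85 ± 0.15, and Lag3, an inhibitory receptor, by 1.00 ± 0.23. Nfkbia, the NF-kB inhibitor IκBα, rose from 153 ± 3.3 to 208 ± 22 CPM, by 0.44 ± 0.09 (edgeR adjusted p = 0.0139). Bhlhe40, a transcription factor of activated T cells, rose by 1.21 ± 0.26, and S100a4, a calcium-binding protein of memory cells, by 0.83 ± 0.16. Selenop, a selenium carrier, Zbtb20, a transcriptional repressor, and Actn1, an actin cross-linker of naive T cells, changed by -0.56, -0.50 and -0.38. The class joined naive cells of cluster 0 with activated or memory cells of clusters 4 and 11, which were 93 of 492 and 113 of 642 in WT and 107 of 605 and 168 of 486 in KO mice, cluster 11 alone 26 and 32 in WT and 58 and 42 in KO mice. Within naive CD4-like cells S100a4 had 1.57 ± 0.47 (edgeR adjusted p = 0.185), and within activated or memory cells Bhlhe40 had 0.93 ± 0.37 and did not pass. In total 67 of 9273 genes changed, 48 higher and 19 lower. Regulatory genes rose in 5 of 15 members and in 7 when adjusted over the list alone (camera adjusted p = 1e-10, and adjusted p = 0.426 with an estimated correlation). Activation and checkpoint genes rose in 3 of 22 members, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2e-05, and adjusted p = 0.433 with an estimated correlation). NF-kB response genes rose in 2 of 27 and in 8 when adjusted over the list alone (camera adjusted p = 3.9e-07, and adjusted p = 0.461 with an estimated correlation). B cell markers rose in 2 of 5 members, and Apoe, a lipoprotein made by macrophages and 36.4 times more abundant in another lineage, rose by 2.02 ± 0.38. DESeq2 called 4 genes, 2 higher and 2 lower, and classes set from marker UMIs also gave 4. The count was 33 when clusters were made without called genes and 125 without KO mouse 1.

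In CD8-like cells (384 to 595 per mouse) 20 of 9213 genes changed, 9 higher and 11 lower. Memory or effector cells were 129 of 384 and 230 of 595 of this class in WT and 126 of 464 and 251 of 416 in KO mice. Ly6a rose from 84.7 ± 16 to 161 ± 20 CPM, a log2 fold change of 0.91 ± 0.12 (edgeR adjusted p = 0.0019), and Plac8, a cysteine-rich protein of lymphoid and myeloid cells, rose by 0.61 ± 0.09. Hsph1 fell from 59.4 ± 13 to 29.3 ± 2.9 CPM, a log2 fold change of -1.04 ± 0.16 (edgeR adjusted p = 0.0057). Fkbp4, a co-chaperone, and Ahsa2, an activator of HSP90, changed by -0.60 ± 0.11 and -1.02 ± 0.21. Ifi27l2a changed by -0.64 ± 0.11, and 1 of 38 interferon response genes fell and 1 rose over all genes, with 6 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.00044, and adjusted p = 0.856 with an estimated correlation). Of the regulatory genes 0 of 16 passed over all genes in edgeR, 2 had an unadjusted p under 0.05 and 1 rose when adjusted over the list alone (camera adjusted p = 0.45). B cell markers rose in 1 of 7 members and in 2 when adjusted over the list alone (camera adjusted p = 0.00044, and adjusted p = 0.856 with an estimated correlation). DESeq2 called 6 genes, marker UMIs gave 5, of which 4 were higher and 1 lower, doublets kept 4, and clustering with expression centred per library 11, of which 7 were higher and 4 lower. The counts without 1 mouse were 49 (WT mouse 1), 53 (WT mouse 2), 153 (KO mouse 1, 86 higher and 67 lower) and 69 (KO mouse 2, 35 higher and 34 lower).

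Within finer classes, naive CD4-like cells had 35 changed genes of 8717, 23 higher and 12 lower, against 21 higher and 21 lower without WT mouse 1. Ly6a rose there by 0.75 ± 0.09 (edgeR adjusted p = 3.1e-06), Socs3, an inhibitor of cytokine signalling, by 0.64 ± 0.12 and Tnip1 by 0.84 ± 0.17. In activated or memory CD4-like cells 1 gene changed, Tpm3-rs7, by 4.86 ± 0.28. An unadjusted p under 0.05 was found for 301 of 6535 genes, about the share that chance alone gives. In cluster 1, CD8-positive cells rich in Ccr7, 12 genes changed, among them Ly6a by 1.33 ± 0.19, Plac8 by 0.86 ± 0.13 and S100a6, a calcium-binding protein 95.1 times more abundant in another lineage, by 2.05 ± 0.41. In memory or effector CD8-like cells 6 genes changed: Cx3cr1, the fractalkine receptor of effector cells, fell from 56.3 to 19.5 CPM, a log2 fold change of -1.67 ± 0.25 (edgeR adjusted p = 0.0056). This class joined clusters 2 and 12, and cluster 12, whose leading genes included Cx3cr1, held 27 of 129 and 70 of 230 of its cells in WT and 22 of 126 and 37 of 251 in KO mice. Within cluster 12, fitted after the data were seen, Cx3cr1 had a log2 fold change of -0.98 ± 0.26 (edgeR adjusted p = 0.642). Hsph1 changed in the class by -1.39 ± 0.21, and Gm2a, a lysosomal activator protein, rose by 0.96 ± 0.16. DESeq2 called 4 (2 higher and 2 lower), 1, 3 and 2 genes in these 4 populations. In activated CD4-like cells the count was 11 without WT mouse 2, 3 without KO mouse 1 and 43 without KO mouse 2; in cluster 1 it was 52 without WT mouse 1, 33 without WT mouse 2 and 41 without KO mouse 2; in memory CD8-like cells it was 58, 29, 28 and 11 without WT mouse 1, WT mouse 2, KO mouse 1 and KO mouse 2.

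Regulatory T-like cells (98 and 140 in WT, 180 and 219 in KO) were made up of clusters 3 and 6, cluster 6 holding most of them in WT and cluster 3 in KO. Penk rose in these cells from 35.4 ± 10 to 258 ± 62 CPM, a log2 fold change of 2.89 ± 0.24 (edgeR adjusted p = 9e-07). Pdcd1 rose by 0.89 ± 0.17, Tnfrsf4 by 0.59 ± 0.11, Tnfrsf9, the receptor 4-1BB, by 0.76 ± 0.15, Icos by 0.61 ± 0.13 and Klrg1 by 0.97 ± 0.19. Itgae, the integrin CD103, rose from 36.7 ± 21 to 93.8 ± 11 CPM, by 1.43 ± 0.28 (edgeR adjusted p = 0.022). Ccr7, the lymph node homing receptor, fell from 103 ± 17 to 47.4 ± 4.9 CPM, a log2 fold change of -1.15 ± 0.22 (edgeR adjusted p = 0.0189), and Foxp1, a transcription factor of quiescence, changed by -0.78 ± 0.14. Notch1, a receptor and reported miR-146a target, rose by 1.06 ± 0.24. In total 42 of 7212 genes changed, 30 higher and 12 lower.

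Of 21 activation and checkpoint genes 5 rose in regulatory T-like cells, and 8 when adjusted over the list alone (camera adjusted p = 2e-09, and adjusted p = 0.306 with an estimated correlation). Of 15 naive T cell genes 2 fell, and 9 when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 2.8e-08, and adjusted p = 0.306 with an estimated correlation). Of 6 B cell markers 3 rose, among them Cd74 by 0.94 ± 0.17 (camera adjusted p = 8.1e-07 for the list, and adjusted p = 0.306 with an estimated correlation). Without WT mouse 2, 3 genes were called, 1 of them among the 42, and classes from marker UMIs gave 2, 1 of them among the 42, while 42 and 40 of the 42 kept their sign. Without WT mouse 2 the signs could hardly turn, since the WT and KO values of all 42 did not overlap. Marker UMIs drew on cells of the same mice, so the kept signs are no separate support. DESeq2 called 12, clusters made without called genes 20, and clustering centred per library 108 (57 higher and 51 lower). The balance turned without WT mouse 1, with 18 higher and 50 lower of 68, and at a minimum of 200 genes per cell, with 64 higher and 83 lower of 147. The count without KO mouse 2 was 66, and in cluster 6 alone Tnfrsf4, Tnfrsf9 and Slamf6 had the opposite sign.

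**Figure D1:**
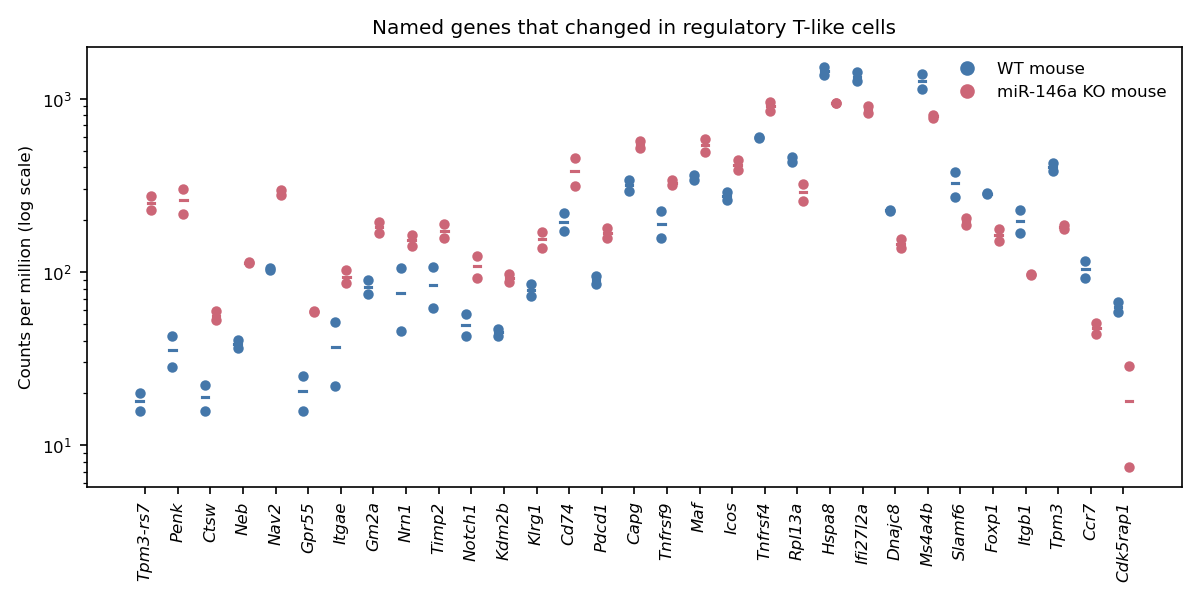
CPM (log scale) of the named genes that changed in regulatory T-like cells; each point is 1 mouse and the short line is the mean of the 2 mice of a genotype. Penk lay at a mean of 35.4 in WT and 258 in KO mice, and Ccr7 at 103 and 47.4.

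**Figure D2:**
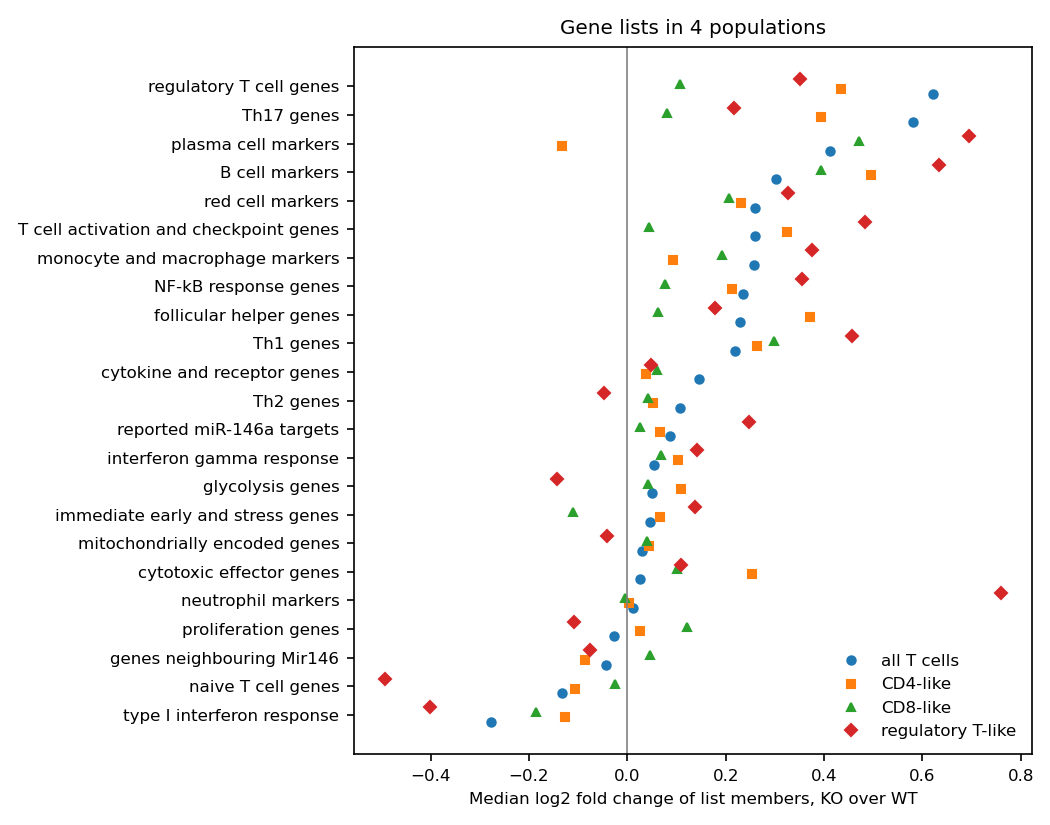
Median log2 fold change (KO over WT) of the tested members of each gene list in 4 populations, with 1 symbol per population. Regulatory T cell genes had a median of 0.62 in all T cells and type I interferon genes of -0.28; no list passed in any of the 4 populations with an estimated correlation or with fry.

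The KO effect differed between CD4-like and CD8-like cells for 4 of 9654 genes by the interaction test. At an unadjusted p under 0.05 there were 514, about the share that chance alone gives. Ikzf2 rose by 0.81 in CD4-like cells and had a log2 fold change of -0.24 in CD8-like cells, a difference of -1.06 ± 0.18 (edgeR adjusted p = 0.0073). In fits chosen after the data were seen, of 2 of the clusters of CD8-like cells, Ikzf2 changed by -1.69 ± 0.23 in cluster 2 (edgeR adjusted p = 5.1e-06) and rose by 2.51 ± 0.38 in cluster 12 (edgeR adjusted p = 0.032), which held 22 to 70 cells per mouse. Nfkbia rose by 0.44 in CD4-like cells and stood at -0.17 in CD8-like cells, a difference of -0.62 ± 0.11 (edgeR adjusted p = 0.0073). Apoe differed by -2.82 ± 0.49. Xcl1, a chemokine of cytotoxic cells, differed by -4.69 ± 0.71, resting on KO mouse 2, which had 171 UMIs of it in CD4-like cells against 9, 0 and 3 in WT mouse 1, WT mouse 2 and KO mouse 1. The count was 31 without KO mouse 1, 10 without WT mouse 1 and 8 without KO mouse 2.

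Reported miR-146a targets were examined as a list, since loss of a microRNA would remove its repression of them. Of 13 tested in all T cells Icos rose, and 2 rose when adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.051). In cluster 1, however, the share of cells with an Icos UMI was lower in both KO mice than in both WT mice. In regulatory T-like cells Icos and Notch1 rose, with a median of 0.25 (camera adjusted p = 0.0026, and adjusted p = 0.306 with an estimated correlation). In CD4-like and CD8-like cells 0 of 13 passed over all genes in edgeR, with 2 and 1 at an unadjusted p under 0.05, and 2 and 0 rose when adjusted over the list alone. Traf6 and Irak1, signalling adaptors of Toll-like receptors, had log2 fold changes of 0.24 ± 0.22 and 0.07 ± 0.08 in all T cells, and Rel, Relb and Cxcr4 had 0.15, 0.37 and -0.15, none of which passed. Genes with a miR-146a seed match in the 3′ UTR (2126) and without one (8154) had mean log2 fold changes of 0.020 and 0.029 in all T cells, a difference of -0.0087 (camera adjusted p = 0.57). The differences were -0.027 in CD4-like, -0.018 in CD8-like and 0.031 in regulatory T-like cells, and none passed.

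The share of cells in each class was compared on clusters made without the called genes. Regulatory T-like cells made up 6.19% and 6.56% of cells in WT and 8.83% and 12.8% in KO mice, a log2 difference of 0.76 ± 0.33 (edgeR adjusted p = 0.428). Interferon-responding T-like cells made up 1.74% and 1.51% in WT and 1.04% and 0.43% in KO mice, a log2 difference of -1.10 ± 0.50 that did not pass. With doublets kept, at a minimum of 200 genes per cell, at resolution 1.5 or at a limit of 5% mitochondrial UMIs, 0 cells fell in a cluster of that name. Other non-T cells, pooled, made up 11.6% and 11.2% in WT and 15.9% and 18.3% in KO mice with clusters from all variable genes. In the same edgeR fits 0 of 14 classes passed, 0 had an unadjusted p under 0.05, and the exact permutation test cannot go under 0.333. Cells with a Foxp3 UMI and no Cd8a or Cd8b1 UMI, Foxp3 being the master regulator of regulatory T cells, were 4.52% and 4.73% of WT and 5.22% and 8.47% of KO cells. With clusters from all variable genes and KO mouse 1 left out, the shares of regulatory and interferon-responding cells and of cluster 1 did pass, at log2 differences of 0.92, -1.75 and -0.87 (edgeR adjusted p = 0.0379 for each).

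**Figure D3:**
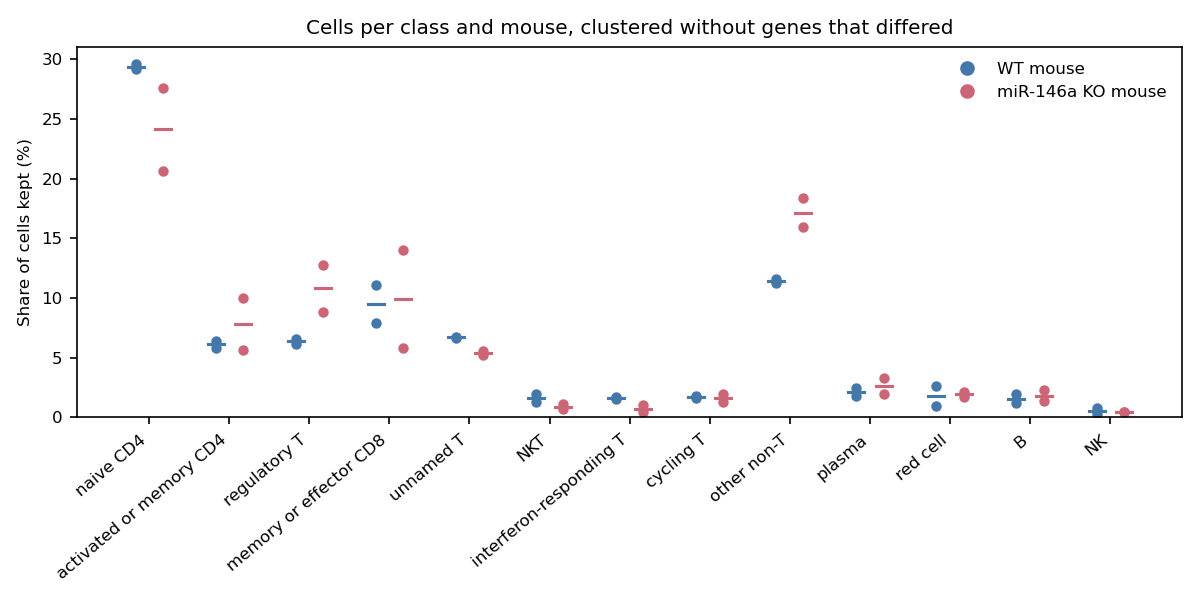
Share of cells kept (percent, linear axis from 0) in each class but naive CD8, with clusters made without the genes that differed. Each point is 1 mouse and the short line is the mean of 2 mice. The class named naive CD8, not plotted, made up 18.9% and 20.1% in WT and 18.3% and 11.2% in KO mice. Regulatory T-like cells lay at 6.19% and 6.56% in WT and at 8.83% and 12.8% in KO mice.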

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

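The tests of more cells in the regulatory clusters and of fewer interferon-responding cells were chosen only after the results were seen, as were the fits of each regulatory cluster alone and of the pooled clusters outside the T cells, and the test of a shift on all 42 genes.

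The knockout effect differed between CD4-like and CD8-like cells, by the interaction test, for Xcl1 (-4.69), Apoe (-2.82), Ikzf2 (-1.06) and Nfkbia (-0.62, log2, CD8 minus CD4). In the pooled clusters 7, 8, 13, 14, 15, 24, 26 and 27, which are outside the T cell comparisons, 6 of 9555 genes changed by edgeR. At an unadjusted p under 0.05 there were 458, about the share that chance alone gives. Tpm3-rs7 (4.57) and Tpm3 (-1.04) changed there as in T cells, as did Wdfy1 (-1.67), a scaffold of endosomal signalling. Pttg1, securin, which holds sister chromatids together, differed by 1.95 there, from 35.7 and 39.5 CPM in WT to 167 and 124 in KO mice. Pttg1 lies on chromosome 11 at 43420250 to 43426251, 45789 bases from Mir146, and had a log2 fold change of -0.09 ± 0.09 (SE) in all T cells. By cluster it was higher in both KO mice in clusters 13, 14, 15 and 24, while in cluster 8 the KO values did not both lie above the WT values, and in clusters 7, 26 and 27 no KO value lay above both WT values. Lrmda (3.68) also changed, from 2 and 3 UMIs in WT to 45 and 56 in KO mice. Cox6a2 (-5.60), a cytochrome c oxidase subunit, changed from 44 and 29 UMIs in WT to 1 in each KO mouse, a KO to WT ratio of 0.0179 in its share of all UMIs (95% exact Clopper-Pearson counting interval 0.00213 to 0.0671). Siglech, a leading gene of cluster 16, which was not among the pooled clusters, and Ly6d, a leading gene of a B cell cluster, had log2 fold changes of -3.05 and -3.13 there (edgeR adjusted p = 0.254 and 0.126). Tcf4, Cd7 and Dntt, genes of plasmacytoid dendritic cells or lymphoid progenitors, had -1.06, -1.66 and -4.99, and did not pass either; these 5 genes were chosen after their values were seen.

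Of 23 regulatory T cell genes 10 rose in all T cells, with a list median of 0.62 (camera adjusted p = 6.2e-35, and adjusted p = 0.229 with an estimated correlation). More cells in the regulatory clusters may account for part of this: without those clusters the median of the 10 called members fell to 0.30 from 0.67. The ratio was 0.447 (95% bootstrap interval 0.135 to 0.738), so how large that part is stays open. Bootstrap intervals here resample genes and not mice, so they carry no spread between mice. Within regulatory cells, a shift from cluster 6 to cluster 3 was tested on the 33 of 42 called genes that were tested in both clusters. Their signed median within the clusters was 0.683 of that in the class (0.565 to 0.869). On all 42 genes it was 0.622 (0.535 to 0.756). The genes were called in these same cells, and some of them, such as Penk and Tnfrsf4, led cluster 3. Values within the clusters are thus not independent of the call, so they cannot decide on the shift. They average both clusters. Over the 42 genes the medians were 0.86 in cluster 3 and 0.46 in cluster 6, where 9 had the opposite sign. A shift as part or the whole of the cause stays possible. More regulatory cells of an unchanged mix would not change levels within the class, where Penk rose by 2.89 ± 0.24 (SE). The mix was not unchanged. Cluster 3, with Penk among its leading genes, held 2.78% and 2.65% of cells in WT and 6.37% and 8.47% in KO mice. Cluster 6 held 4.03% and 4.63% in WT and 3.03% and 4.88% in KO mice. The mix may therefore account for part of the rise of Penk in the class. A response to the loss of miR-146a stays open there, as untested.

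Of 43 type I interferon genes 5 fell and 1 rose in all T cells, with a list median of -0.28 (camera adjusted p = 1.5e-14, and adjusted p = 0.229 with an estimated correlation). KO mouse 2 alone did not carry it in these data, since without that mouse the median of 43 genes was -0.24 against -0.28, a ratio of 0.879 (0.557 to 1.38). The intervals resample genes and not mice, so they carry no spread between mice, and here 1 KO mouse was left. Fewer interferon-responding cells may account for part: without cluster 9 the ratio was 0.576 (0.203 to 0.866), which leaves open how much. The genotype itself remains an untested explanation.

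The same 15 genes changed alike in CD4-like and CD8-like cells, among them Tpm3-rs7, Tpm3, Ide, Cdk5rap1 and Slc15a2, a peptide transporter chosen here after its values were seen, with 41 and 14 UMIs in WT and 0 in both KO mice in CD4-like cells. For Tpm3 and Tpm3-rs7 the summed counts had a log2 fold change of 0.042 (SE 0.066), as reads of 1 transcript divided differently between related sequences would give, for example through a sequence variant, which was not looked for. A segment of another strain may explain others: 1 of the 15 lies within 20 Mb of Mir146 (permutation p = 0.268), which does not decide. Only 1 pair lies within 5 Mb (permutation p = 0.468). It is Iglc2 and Iglc1, neighbouring immunoglobulin genes on chromosome 16, so it says little about such segments. Of the 15, these 2 are at least 20 times more abundant in another lineage, so free RNA may explain them and leaves the rest open. In CD4-like and CD8-like cells Iglc2 rose by 1.93 and 2.41, while Iglc1 changed by -1.05 and -1.18. An excess of free RNA in KO mice that was equal for all genes would not give both directions, but an uneven one could.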

How the results depend on the processing

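Added after seeing the data were the clusters made without called genes, the fits without genes abundant in other lineages or without the regulatory or interferon-responding clusters, the separate fits of clusters 3 and 6 and of clusters 2 and 12, and shares of T cells. Among values of named genes under all alternatives, 1653 kept their direction and side of the threshold, 469 no longer passed, 5 newly passed and 31 changed sign. Among counts, lists and shares, 230 stayed, 78 moved, 3 newly passed and 17 changed sign. Why a value moved was not tested except where stated: the cause was not tested. Fits without 1 mouse leave 1 mouse in a group, which is assumed to vary like the other group. A limit of 5% mitochondrial UMIs was not run for CD4-like, CD8-like and regulatory T-like cells, where a mouse had fewer than 50 cells.

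DESeq2 called 38 genes in all T cells, 4 in CD4-like, 6 in CD8-like, 12 in regulatory T-like, 4 in naive CD4-like, 3 in cluster 1 and 2 in memory or effector CD8-like cells. With no filter on low counts, which tests more genes, the counts were 278 in all T cells, 111 in CD4-like, 82 in CD8-like, 139 in regulatory T-like, 68 in naive CD4-like, 29 in activated or memory CD4-like, 44 in memory or effector CD8-like cells and 48 in cluster 1, and 12 for the difference between CD4-like and CD8-like cells. Robust estimation gave 142 in all T cells and 85 in regulatory T-like cells. The limit of 5% mitochondrial UMIs gave 3 in all T cells, and leaving out the regulatory clusters gave 20.

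Classes from marker UMIs gave 4 genes in CD4-like, 5 in CD8-like and 2 in regulatory T-like cells. Clusters without called genes gave 33, 12 and 20. Expression centred per library gave 11 in CD8-like and 108 in regulatory T-like cells. In CD8-like cells, doublets kept gave 4 and a minimum of 200 genes gave 5. In regulatory T-like cells, a minimum of 200 genes gave 147 (64 higher and 83 lower), Leiden resolution 1.5 gave 82, cluster 3 alone 14 and cluster 6 alone 2. Of the memory or effector CD8-like clusters, cluster 2 alone gave 25 and cluster 12 alone 2.

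With the mouse number as a replicate block the counts were 467 in all T cells, 162 in CD4-like, 126 in CD8-like, 155 in regulatory T-like, 98 in naive CD4-like, 19 in activated or memory CD4-like and 58 in memory or effector CD8-like cells and 64 in cluster 1, and the log2 difference in the share of memory or effector CD8-like cells was -0.030. In the labels the mice share only a number, and no batch is given. The differences between mouse 1 and mouse 2 in the WT and KO groups had a correlation of 0.073 across 8511 genes, which are not independent replicates. So low a value cannot exclude a shared batch that acts on some genes only.

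Leaving out 1 mouse at a time gave 55 to 511 genes in all T cells, 58 to 125 in CD4-like, 49 to 153 in CD8-like, 3 to 68 in regulatory T-like, 1 to 43 in activated or memory CD4-like, 11 to 58 in memory or effector CD8-like cells, 10 to 52 in cluster 1 and 6 to 31 for the difference between CD4-like and CD8-like cells. The highest counts came without KO mouse 1 in all T, CD4-like and CD8-like cells and for the difference, and without WT mouse 1 in regulatory T-like cells, memory or effector CD8-like cells and cluster 1. The lists passing by camera numbered 13 in all T, 12 in CD4-like, 5 in CD8-like and 15 in regulatory T-like cells, and 0 with an estimated correlation and 0 with fry in each. At an unadjusted p under 0.05 they numbered 4, 2, 0 and 2 with an estimated correlation and 6, 2, 1 and 4 with fry. In CD8-like cells they numbered 7 to 9 without 1 mouse, 9 without KO mouse 1 and 8 without WT mouse 1 or 2. With matched UTR lengths the difference by seed match in all T cells was 0.00032.

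No class share passed with all 4 mice in edgeR. The share of interferon-responding cells had no value with doublets kept, at a minimum of 200 genes, at resolution 1.5 or at a limit of 5% mitochondrial UMIs, where 0 cells were in a cluster of that name. The log2 difference in the share of cycling T-like cells was 0.07, against -0.00059 with doublets kept and -0.064 with clusters without called genes, and -0.27 to 0.32 without 1 mouse. At a limit of 5% mitochondrial UMIs it was -1.24 for memory or effector CD8-like and -0.29 for plasma cells. Without 1 mouse the differences ranged from -0.14 to 0.73 in activated or memory CD4-like, -0.19 to 0.61 in B, -1.75 to -0.58 in interferon-responding, -0.68 to 0.54 in memory or effector CD8-like, -0.97 to 0.59 in NK, -0.11 to 0.65 in plasma, -0.49 to 0.96 in red and 0.41 to 0.92 in regulatory T-like cells, and from -0.87 to -0.058 in cluster 1. Those of -1.75, 0.92 and -0.87 passed, without KO mouse 1.

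At the limit of 5% mitochondrial UMIs Ifit1 stood at 0.20 and Cxcr4 at 0.0076 in all T cells. With marker UMIs Irak1 stood at 0.20 and Rel at 0.0039 in CD4-like cells, Cxcr4 at 0.057 and Irak1 at 0.060 in CD8-like cells, and Cxcr4 at -0.26 in regulatory T-like cells. Rel in CD4-like cells stood at 0.061 with a minimum of 200 genes and at 0.0057 at resolution 1.5. In cluster 6 alone Tnfrsf4 stood at -0.23, Tnfrsf9 at -0.28, Slamf6 at 0.083, Rel at -0.31 and Relb at -0.27. Cxcr4 in regulatory T-like cells stood at -0.099 with clusters without called genes and at -0.17 in cluster 3 alone. Without 1 mouse, genes that had not passed spanned 0: in all T cells Cxcr4 from -0.36 to 0.058 and Traf6 from -0.027 to 0.61. In CD4-like cells Cxcr4 ranged from -0.54 to 0.32, Irak1 from -0.14 to 0.068 and Rel from -0.15 to 0.12. In CD8-like cells Rel ranged from -0.070 to 0.19 and Traf6 from -0.65 to 0.67, and in regulatory T-like cells Cxcr4 from -0.51 to 0.70 and Relb from -0.059 to 0.12.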

Other observations

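No test in this part was chosen after the results were seen. Of 9 tested Th17 genes Maf rose in all T cells, and 4 rose when adjusted over the list alone, with a median log2 fold change of 0.58 (limma camera adjusted p = 4.2e-08, and adjusted p = 0.229 with an estimated correlation). Of 18 follicular helper genes 3 rose, and 3 rose and 2 fell when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00012, and adjusted p = 0.293 with an estimated correlation). Cluster 11, with Il21 and Pdcd1 among its leading genes, made up 1.81% and 1.66% of cells in WT and 3.03% and 2.56% in KO mice, a difference that was not tested for this cluster alone. Of 18 Th1 genes 0 passed by edgeR, also when adjusted over the list alone, and 8 had an unadjusted p under 0.05, with a median of 0.22 (camera adjusted p = 0.015, and adjusted p = 0.6 with an estimated correlation). Of 8 Th2 genes 0 passed by edgeR and 4 had an unadjusted p under 0.05, and 1 rose and 1 fell when adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.431). Of 25 cytotoxic effector genes Klrg1 rose and Cx3cr1 fell (-1.46 ± 0.27, SE), and the median was 0.02 (camera adjusted p = 0.417). Of 30 proliferation genes 0 passed by edgeR and 0 had an unadjusted p under 0.05, with a median of -0.03 (camera adjusted p = 0.417).

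In naive CD4-like cells Zbtb20 fell by 0.64 on the log2 scale, and in regulatory T-like cells Itgb1, the integrin beta 1 chain, fell from 197 to 96.5 CPM (log2 fold change -1.01 ± 0.18, SE). In all T cells Stip1, a co-chaperone of HSP70 and HSP90, changed by -0.55 ± 0.10, and in regulatory T-like cells Hspa8, a constitutive HSP70, changed by -0.62. The list of immediate early and stress genes had 1 member higher (Junb) and 1 lower (Dnaja1) of 22 in all T cells, with 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.647).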
